A study of Mus musculus with 8 samples.

How the data were processed

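RNA sequencing of the mouse macrophage-like line RAW264.7, a line transformed with Abelson leukaemia virus, was analysed from 8 libraries in 4 groups of 2. The groups were untreated cells, cells given lipopolysaccharide (LPS), cells given antibodies against CD36 and cells given both. Per the labels, LPS was used at 50 ng/mL and the antibodies at a dilution of 1 in 100, each for 12 h. The labels of the combination give 12 h but no doses. Per the labels' protocols, total RNA was taken with Trizol and made into libraries by a standard Illumina protocol. The labels also name the 10x Genomics platform, but the table holds 1 value per gene and library, and it was treated as bulk RNA sequencing. Samples were placed in groups and replicates by their labels alone.

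The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to a total of reads of each library), with 1 column per library. The submitters' processing notes name HISAT2 2.0.5 and the builds mm10 and hg38. The role of hg38, the read counter, the gene annotation, strand use and the treatment of reads with several matches were not given in the sources used here. The table held 10639 genes by symbol. None was at 0 in any library, so a gene at 0 in any of the 8 libraries was not analysed here. The genes stood in order of the ratio of the combination mean to the LPS mean, with 0 out of order. Values of genes with near-identical copies elsewhere in the genome, such as ribosomal protein genes, mitochondrial genes and Ifit3, and of genes that overlap others, are uncertain because the counting rule is not known. Of the symbols, 10556 were in the RefSeq gene table and 10376 in GENCODE M21 (GRCm38, the same assembly as mm10), from which coordinates and GC content were taken. No library column was left unused.

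Depth was recovered from the values. In 96 short RNAs the FPKM steps of single reads were visible, and 73 to 75 of them per library came out as whole reads within 0.02. Rounded, this gave 55700000 and 71700000 reads for the untreated libraries, 61400000 and 63600000 for LPS, 47900000 and 57400000 for anti-CD36, and 61100000 and 53500000 for the combination. A counted length was then found for 10638 genes, with a median ratio to the GENCODE M21 union exon length of 1.0 and a Spearman rho of 0.994 across genes. At these depths, 3 reads in a gene of 2000 bp equal an FPKM of 0.0209 to 0.0313. That floor covers counting error only.

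FPKM values are not counts, so the test was linear modelling with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 10289. A model with 4 group means was fitted to all 8 libraries, which share 1 estimate of the spread (4 residual and 3.46 prior degrees of freedom, empirical Bayes with a trend on mean expression). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The comparisons were LPS, anti-CD36 and the combination each against untreated cells, the combination against LPS, the combination against anti-CD36, and the interaction, which is the LPS effect with the antibody minus the LPS effect without it. Nothing in the labels says that the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

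Before the data were examined, 32 gene lists were fixed for macrophage activation, lipid handling, metabolism, stress, markers of other cell types and RNA quality. The 26 lists with at least 5 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members absent from the deposited table or under the expression filter could not be tested, so the number tested is given with each list. Whether an absent member was at 0 in a library or was left out of the table for another reason is not known.

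The genes named in the text were chosen by a rule set at the same time. It takes the 10 largest rises and 10 largest falls among called genes whose replicate ranges do not overlap and whose mean FPKM over the compared libraries is at least 5. Pseudogenes, predicted genes and genes with no symbol were left out. The rule adds Cd36 and Tlr4 in each comparison and up to 4 members of each list with the largest absolute difference. Other called members of lists with few calls, and the genes called higher in both antibody comparisons, were chosen after their values were seen. Some genes that the rule takes are not reported here.

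The alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, quantile normalization, median-ratio size factors, no trend, a fit on only the groups compared, a log2 difference of at least 1, a replicate block, and each library left out in turn. Leaving out mitochondrial genes and removing each library's trend with gene length or GC content (lowess, span 0.3) were added after seeing the data. The model was tested on simulated data with 200 of 10289 genes changed. In the comparison of the combination with LPS it recovered 18%, 76%, 94% and 100% of genes changed by 0.5, 1, 2 and 4 on the log2 scale. For anti-CD36 against untreated cells it recovered 20%, 70%, 94% and 100%, and for LPS against untreated cells 28%, 68%, 90% and 100%. The simulation drew genes independently and gave every library the same spread for a gene. In the data, the SD of the replicate difference over genes was 0.451 with anti-CD36 and 0.137 with LPS. The recovered shares therefore do not show how the comparisons differ in what they can detect. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.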

Results

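Gene expression was measured in RAW264.7 macrophages that were untreated, given LPS, the bacterial cell wall component sensed through TLR4, given antibodies against CD36, a scavenger receptor for oxidized lipoproteins and long-chain fatty acids, or given both. Each group had 2 libraries, of 47900000 to 71700000 reads by the recovered depth. Replicates correlated at 0.992 in untreated cells, 0.997 with LPS, 0.966 with anti-CD36 and 0.994 with both (Pearson's r of log2 values across genes, which are not independent replicates). The anti-CD36 libraries did not group apart from the untreated ones by this measure, since replicate 1 correlated with the untreated libraries at 0.972 and 0.979 and replicate 2 at 0.973 and 0.957. The LPS and combination libraries did, at 0.984 to 0.988 with each other. The SD of the replicate difference over genes was 0.22, 0.14, 0.45 and 0.19 on the log2 scale in the same order. Mitochondrial genes held 15.8% of the summed FPKM in anti-CD36 replicate 1 and 6.59% in replicate 2, against 4.7% and 6.62% in untreated cells, 4.1% and 3.94% with LPS, and 3.28% and 4.47% with both. Few markers of other cell types were among the tested genes. None of the fibroblast, epithelial and endothelial markers was tested, 1 each of the granulocyte (Csf3r), T and NK cell (Lck) and dendritic cell (Fscn1) markers was, and 2 of the B cell markers were (Cd79b and Ighm). With LPS, Fscn1 (log2 difference 1.30), Lck (0.84) and Cd79b (0.84) were called higher, while Csf3r and Ighm were not called. Ighm was abundant in every group, at an FPKM of 86.0 untreated, 76.5 with LPS, 88.9 with anti-CD36 and 79.9 with both. The FPKM of Fscn1 was 0.0639 untreated, 1.61 with LPS, 0.168 with anti-CD36 and 2.86 with both, and Fscn1 was also higher in the combination than in LPS (0.56, limma adjusted p = 0.031). Lck went from 1.94 to 4.27 with LPS and Cd79b from 0.0913 to 0.969, and none of these 5 genes was called with anti-CD36 alone.

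Cd36 itself (chromosome 5, 17781690 to 17888801, minus strand, GRCm38, protein-coding) was close to the floor in untreated cells, at an FPKM of 0.0783 ± 0.0541 (SD, n = 2), from about 8 and 30 reads. It rose to 5.14 ± 0.603 with LPS, a log2 difference of 2.51 ± 0.11 (SE, limma adjusted p = 6.4e-06). With anti-CD36 alone it was at 0.196 ± 0.0386, which was not called (log2 difference 0.15, limma adjusted p = 0.41). With both it stood at 8.53 ± 0.774, above LPS alone by 0.64 ± 0.11 (limma adjusted p = 0.0449). That last call was lost without either untreated library, either LPS library or either combination library. The difference itself stayed at 0.535 to 0.736 over the 8 fits with 1 library left out. The call was also lost with a pseudocount of 0.1 (limma adjusted p = 0.169) and with mitochondrial genes left out (0.0537). Tlr4, the LPS receptor (chromosome 4, 66827584 to 66930284, plus strand, GRCm38, protein-coding), fell with LPS from 7.93 ± 1.06 to 3.19 ± 0.69 (log2 difference -1.10 ± 0.15, limma adjusted p = 0.00067). It was at 7.42 ± 0.438 with anti-CD36 and 2.23 ± 0.206 with both, and neither differed by the test from its counterpart without the antibody.

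**Figure D1:**
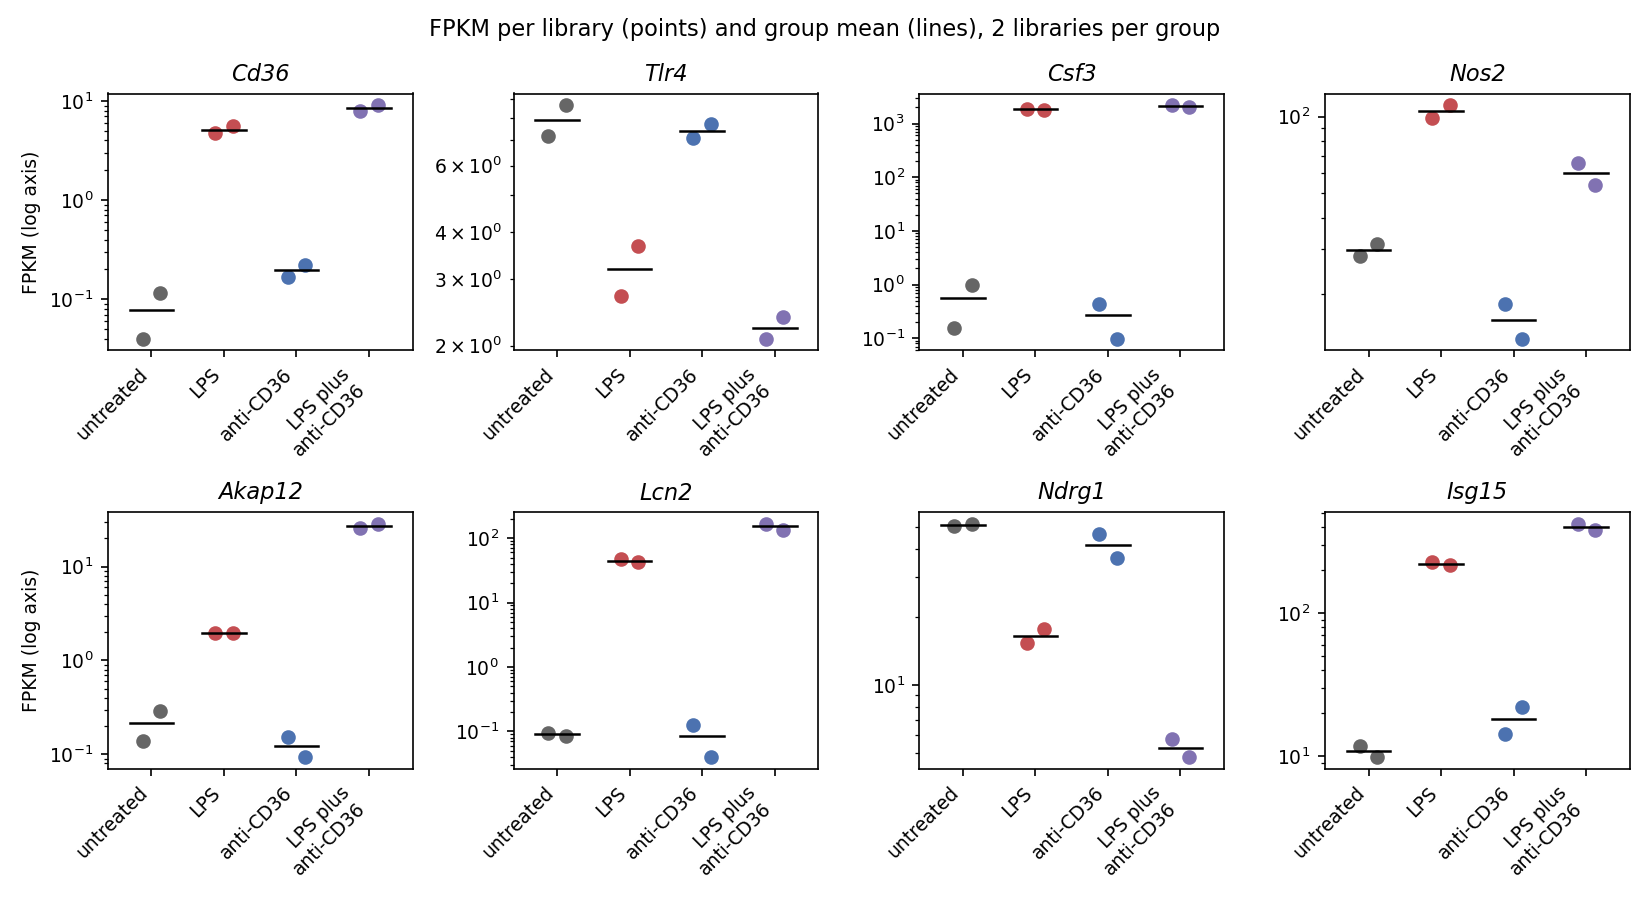
FPKM (log axis) of Cd36, Tlr4, Csf3, Nos2, Akap12, Lcn2, Ndrg1 and Isg15 in untreated, LPS, anti-CD36 and combination libraries, with points for single libraries and lines for the means of 2. Akap12 stands at a mean of 27.2 with both treatments and 1.96 with LPS alone, and Ndrg1 at 5.26 and 16.5.

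The LPS comparison asks how the cells respond to endotoxin. Csf3, the granulocyte colony-stimulating factor, went from an FPKM of 0.575 ± 0.597 to 1853 ± 52.8 (log2 difference 10.26 ± 0.25). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 9.62 ± 0.31, the cytokine Il1b by 9.45 ± 0.11 and the chemokine Ccl5 by 9.20 ± 0.28. The largest falls were in Ranbp3l (-3.94 ± 0.15), Selenbp1 (-3.53 ± 0.26), Scel (-3.40 ± 0.25) and Alox5 (-3.13 ± 0.14), which makes leukotrienes. The limma adjusted p of these 8 genes ran from 2.3e-08 for Il1b to 4.5e-05 for Selenbp1.

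All 14 tested inflammatory cytokines rose with LPS (14 adjusted over the list alone), among them Il1a (7.43) and Lif (6.71), and the list passed camera at an adjusted p of 6.35e-16 (adjusted p = 0.0156 with an estimated correlation). Of 11 chemokines, 10 rose (10 adjusted over the list alone), with Cxcl2 at 8.55, Ccl3 at 7.03, Ccl4 at 6.92 and Ccl22 at 6.59 (camera adjusted p = 3.09e-11, and adjusted p = 0.0456 with an estimated correlation). Of 40 interferon-stimulated genes, 32 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 8.74e-16, and adjusted p = 0.0156 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 4.27, the ubiquitin-like Isg15 by 4.24 and the guanylate-binding protein Gbp3 by 3.65. Nitric oxide, prostaglandin and antimicrobial effectors rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 4.93e-10, and adjusted p = 0.034 with an estimated correlation). These included Acod1, which makes itaconate (6.17), Lcn2, which binds bacterial siderophores (5.38), and Saa3 (5.32). Of 22 NF-kB pathway and feedback genes, 18 rose (18 adjusted over the list alone, camera adjusted p = 1.34e-14), led by Nfkbiz (4.69) and Socs3 (3.30). That call was lost at an adjusted p = 0.0554 with an estimated correlation.

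Genes of cell division fell with LPS in 34 of 36 (35 adjusted over the list alone, camera adjusted p = 6.65e-10, but adjusted p = 0.0554 with an estimated correlation). The mitotic kinase Plk1 changed by -2.26, the kinesin Kif20a by -2.08 and Aurkb by -1.92. Cholesterol synthesis genes fell in 20 of 24 (20 adjusted over the list alone, camera adjusted p = 0.000107, but adjusted p = 0.122 with an estimated correlation), with Sqle, the squalene epoxidase, at -1.61. Of 24 glycolysis and hypoxia genes, 14 fell and 2 rose (15 and 2 adjusted over the list alone, camera adjusted p = 0.0302, but adjusted p = 0.53 with an estimated correlation). Ankrd37 changed by -2.40, Bnip3 by -1.76 and Ndrg1 by -1.58, and the list's call was lost without untreated replicate 1 (adjusted p = 0.054). Immediate early genes rose in 14 of 20 and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 1.02e-08, but adjusted p = 0.206 with an estimated correlation), including the phosphatase Dusp2 (3.77) and the mRNA decay factor Zfp36 (3.70). Antigen presentation genes rose in 12 of 17 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 4.33e-06, but adjusted p = 0.208 with an estimated correlation), with the costimulatory molecules Cd40 at 4.60 and Cd80 at 2.43. Of 20 genes for Fc receptors, phagocytosis and integrins, 12 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.000526, but adjusted p = 0.208 with an estimated correlation). The inhibitory receptor Fcgr2b rose by 1.99 and Fcgr3 changed by -1.85. Of 15 p53 targets, 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000485, but adjusted p = 0.145 with an estimated correlation), with Plk2 at 4.65 and the death receptor Fas at 2.38. Ribosomal protein genes rose in 8 of 25 (2 adjusted over the list alone, camera adjusted p = 3.13e-06, but adjusted p = 0.525 with an estimated correlation), such as Rpl37 (1.43). They held 12.7% and 11.9% of FPKM with LPS and 9.56% and 7.72% in untreated cells.

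Several lists moved in both directions with LPS and were not called. Lipid handling genes of PPARg and LXR fell in 11 of 20 and rose in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.219), with the fatty acid synthase Fasn at -2.26, the desaturase Scd1 at -2.14 and the lipid carrier Fabp4 at 3.13. Of 9 scavenger receptors, 3 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.97), Msr1 by 2.97 and Lrp1 by -1.84. The list's median was -0.63 and its mean 0.11. Of 22 TLR signalling genes, 6 rose and 10 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.987, upward although the median was -0.26). Macrophage identity genes rose in 6 of 18 and fell in 6 (6 and 7 adjusted over the list alone, camera adjusted p = 0.576), the surface receptor Adgre1 by 2.59 and the fractalkine receptor Cx3cr1 by -2.05. The other camera adjusted p-values were 0.053 for osteoclast genes, which include the protease Mmp9 (4.15), 0.182 for the unfolded protein response, 0.226 for the inflammasome, 0.26 for NRF2 targets, 0.45 for alternative activation, 0.549 each for fatty acid oxidation and for heat shock and housekeeping genes, 0.585 for mitochondrial transcripts and 0.987 for lysosomal genes.

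LPS changed 5614 of 10289 genes (limma, Benjamini-Hochberg), 1754 upward and 3860 downward, and 1712 of them by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 6267, where chance gives 514. The share of rises moved with scaling, from 31.2% as deposited to 49.6% with size factors (2666 up and 2708 down of 5374) and 44.6% after quantile normalization (2444 up and 3037 down of 5481), since the median of all genes was -0.19 as deposited and 0.01 with size factors. Without LPS replicate 1 the count was 3598.

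With anti-CD36 alone fewer genes were called, and with smaller differences. Lrp1, the lipoprotein receptor-related endocytic receptor, fell from an FPKM of 46.4 ± 4.57 to 17.4 ± 5.16 (log2 difference -1.39 ± 0.20). Falls were also found in Pdpr, a regulator of pyruvate dehydrogenase phosphatase (-1.47 ± 0.11), Ago2, the core protein of small RNA silencing (-1.35 ± 0.14), and Dync1h1, the dynein heavy chain (-1.28 ± 0.21). The inducible nitric oxide synthase Nos2 fell from 29.9 ± 2.37 to 15.8 ± 3.43 (-0.90 ± 0.17). Among the rises were Spink5 (9.48 ± 2.58 to 25.6 ± 2.04, log2 difference 1.37 ± 0.18), Anxa1, a regulator of phagocyte responses (1.01 ± 0.21), and the mitochondrially encoded ND4 (1.36 ± 0.36) and COX2 (1.24 ± 0.21). The limma adjusted p was 0.011 for Pdpr and Ago2, 0.022 for Nos2, 0.014 for Spink5 and 0.048 for ND4. These values rest on a spread shared with the LPS groups, whose replicates lay closer together. In a fit on only the groups compared, none of these genes was called. Differences in this comparison also followed gene length (Spearman rho -0.445 across genes).

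Lipid handling genes of PPARg and LXR fell with anti-CD36 in 9 of 20 and rose in none (10 adjusted over the list alone). Scd1 changed by -0.96, Scd2 by -0.93, Fasn by -0.80 and Acaca, the acetyl-CoA carboxylase, by -0.80. The list passed camera at an adjusted p of 0.00355 (adjusted p = 0.222 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 24 (7 adjusted over the list alone), among them Srebf2, the transcription factor of the pathway (-0.72), but the list was not called (camera adjusted p = 0.135). Interferon-stimulated genes rose in 4 and fell in 2 of 40 (4 and 2 adjusted over the list alone, camera upward at an adjusted p of 9.01e-05, but adjusted p = 0.222 with an estimated correlation). Phf11d was up by 0.73 and Ifi44 by 0.66, while Stat2, a transcription factor of the interferon response, was at -0.65. Pyroptosis genes rose in 4 of 14 (4 adjusted over the list alone, camera adjusted p = 0.0798), the inflammatory caspases Casp1 by 0.87 and Casp4 by 0.66, with Casp8 at 0.54 and the pore-forming Gsdme at 0.48. Of the inflammatory cytokines, 1 of 14 was called (1 adjusted over the list alone, camera adjusted p = 0.406), Il18 at 0.54.

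Mitochondrial transcripts rose in 3 of 13 (8 adjusted over the list alone, median 1.06, camera adjusted p = 7.83e-07, but adjusted p = 0.621 with an estimated correlation), and anti-CD36 replicate 1 alone held 15.8% of its FPKM in mitochondrial genes. Ribosomal protein genes had 0 of 25 called (0 adjusted over the list alone, camera adjusted p = 3.2e-05 upward, but adjusted p = 0.691 with an estimated correlation). Their call was lost without anti-CD36 replicate 2 (adjusted p = 0.482) and after quantile normalization (0.099), and they held 7.75% and 13.1% of FPKM in the anti-CD36 replicates. Heat shock and housekeeping genes had 1 of 12 called (1 adjusted over the list alone, camera adjusted p = 0.00516, but adjusted p = 0.222 with an estimated correlation), the chaperone Hsp90aa1 at 0.99, and lost the call without anti-CD36 replicate 1 (0.105) and after quantile normalization (0.513). Cell cycle genes had 3 of 36 higher and 1 lower (3 and 1 adjusted over the list alone, camera upward at an adjusted p of 0.0212, but adjusted p = 0.621 with an estimated correlation), such as Bub1 (0.64) and Top2a (0.60). This call was lost without anti-CD36 replicate 1 (0.222) and after quantile normalization (0.423). None of 11 chemokines was called (0 adjusted over the list alone, camera adjusted p = 0.0212, but adjusted p = 0.621 with an estimated correlation). That list's call was lost without untreated replicate 2 (0.0888), anti-CD36 replicate 1 (0.0755) or anti-CD36 replicate 2 (0.0573), after quantile normalization (0.064) and with the length trend removed (0.361).

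With anti-CD36, 1405 of 10289 genes were called (limma, Benjamini-Hochberg), 313 higher and 1092 lower, and 61 of them by at least 1. At an unadjusted p under 0.05 there were 3210, where chance gives 514. The share of rises was 22.3% as deposited, 42.3% with size factors (430 up and 586 down of 1016) and 42.1% after quantile normalization (465 up and 639 down of 1104). Called falls had a median counted length of 7301 bp against 4329 bp for all tested genes, and the difference correlated with length at a Spearman rho of -0.445 across genes. Replicate differences followed length too, at -0.478 between the untreated replicates, -0.244 with LPS, 0.322 with anti-CD36 and -0.283 with both. The count rests on the spread shared with the LPS groups. In a fit on only the groups compared no gene was called (2045 at an unadjusted p under 0.05). Without untreated replicate 1 or 2 none was called either (2336 and 2033), without LPS replicate 1 or 2 the counts were 324 and 325, without combination replicate 1 or 2 they were 467 and 505, and without anti-CD36 replicate 1 or 2 they were 3730 and 2823. None of the 4 groups received an antibody of another specificity.

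The combination against LPS asks what the antibodies change in LPS-treated cells. Akap12, a scaffold for protein kinases A and C (chromosome 10, 4266380 to 4359470, plus strand, GRCm38, protein-coding), rose most, from an FPKM of 1.96 ± 0.0213 to 27.2 ± 2.19 (log2 difference 3.25 ± 0.11, limma adjusted p = 5e-05). Lcn2 rose from 44.4 ± 3.18 to 152 ± 22.7 (1.74 ± 0.13, limma adjusted p = 0.0088), and the metalloproteinase inhibitor Timp1 from 25.4 ± 1.37 to 84.8 ± 1.48 (1.70 ± 0.15). The chemokine Ccl22 was higher by 1.19 ± 0.14, the transcription factor gene Fos by 1.25 ± 0.18 and Il1a by 0.98 ± 0.14. Ndrg1 fell from 16.5 ± 1.65 to 5.26 ± 0.693 (-1.49 ± 0.15, limma adjusted p = 0.012), the mitophagy receptor Bnip3 from 39.1 ± 8.73 to 14.3 ± 0.429 (-1.37 ± 0.17) and Ero1a, an oxidase of the endoplasmic reticulum, from 110 ± 10.5 to 44.6 ± 0.625 (-1.28 ± 0.13). Other falls were in the potassium channel Kcnj2 (-1.45), the urokinase Plau (-1.38), the mitophagy receptor Bnip3l (-1.26), the adenylate kinase Ak4 (-1.19), the peptide adrenomedullin Adm (-1.17) and the copper transporter Atp7a (-1.15).

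Of 24 glycolysis and hypoxia genes, 5 fell in the combination (10 adjusted over the list alone). Besides Ndrg1 and Bnip3 they were Pdk1, which restrains pyruvate dehydrogenase (-0.90), and the glycolytic Pfkfb3 (-0.77) and Pfkp (-0.72). The list's median was -0.43 (camera adjusted p = 7.03e-09, but adjusted p = 0.262 with an estimated correlation). Interferon-stimulated genes rose in 3 of 40 (13 adjusted over the list alone), Oasl1 by 0.97, Ifit3 by 0.75 and Gbp3 by 0.73. Their median was 0.29 (camera adjusted p = 3.01e-09, but adjusted p = 0.0831 with an estimated correlation). Isg15 was at 221 ± 6.47 with LPS and 400 ± 30.9 with both, a difference that was not called (limma adjusted p = 0.078). Nitric oxide, prostaglandin and antimicrobial effectors rose in 3 of 18 (5 up and 1 down adjusted over the list alone), Lcn2, the arginine-recycling enzyme Ass1 (0.77) and the histamine-forming Hdc (0.67). The camera adjusted p was 0.000989 (adjusted p = 0.217 with an estimated correlation). Nos2 stood at 105 ± 8.33 with LPS and 59.7 ± 8.16 with both (log2 difference -0.81 ± 0.17), which missed the threshold (limma adjusted p = 0.066).

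Chemokines had 1 of 11 called, Ccl22 (1 adjusted over the list alone, camera adjusted p = 0.00223, but adjusted p = 0.262 with an estimated correlation). The call was lost without LPS replicate 2 (adjusted p = 0.0629) and with the length trend removed (0.0848). Inflammatory cytokines had 1 of 14 called, Il1a (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.027, but adjusted p = 0.262 with an estimated correlation). This was lost without LPS replicate 2 (0.0731), with a pseudocount of 0.1 (0.12), after quantile normalization (0.26) and with the length trend removed (0.374). Il1b was at 871 ± 41.0 with LPS and 1189 ± 45.9 with both (limma adjusted p = 0.093), and Ptgs2 at 2132 ± 150 and 1453 ± 164 (0.38). Antigen presentation genes had 1 of 17 called, Cd80 at 0.69 (2 adjusted over the list alone, camera adjusted p = 0.00223, but adjusted p = 0.58 with an estimated correlation). Lipid handling genes of PPARg and LXR had 1 of 20 called, Scd2 at -0.84 (8 lower adjusted over the list alone, median -0.23, camera adjusted p = 0.00594, but adjusted p = 0.217 with an estimated correlation). Immediate early genes went both ways, with Fos and the quiescence factor Klf2 (0.90) higher and Egr3 (-0.92), Myc (-0.87) and Klf6 (-0.71) lower (3 up and 6 down adjusted over the list alone of 20, camera adjusted p = 0.825). Of 22 NF-kB pathway genes, the subunit Rel (-0.84) and the caspase inhibitor Cflar (-0.93) fell (3 up and 4 down adjusted over the list alone, camera adjusted p = 0.212). None of 36 cell cycle genes (camera adjusted p = 0.33), 24 cholesterol synthesis genes (0.289) or 13 mitochondrial transcripts (0.104) was called, and 0 of each adjusted over the list alone.

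**Figure D2:**
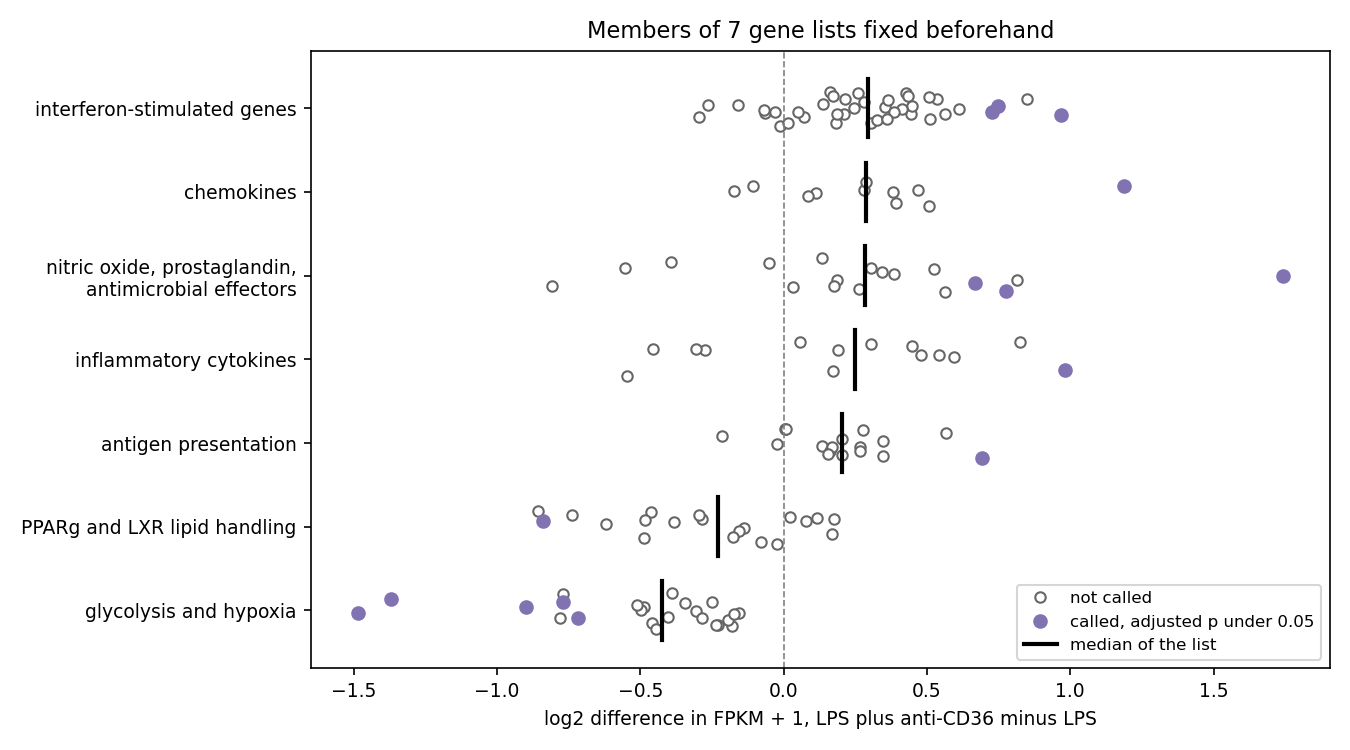
Log2(FPKM + 1) difference between the combination and LPS (axis) for each tested member of the 7 gene lists that passed camera, with filled points for called genes and black bars for list medians. The glycolysis and hypoxia genes have a median of -0.43 and the interferon-stimulated genes a median of 0.29.

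In the combination, 183 of 10289 genes differed from LPS (limma, Benjamini-Hochberg), 37 higher and 146 lower, and 37 of them by at least 1. At an unadjusted p under 0.05 there were 2005, where chance gives 514. The share of rises was 20.2% as deposited, 29.4% with size factors (55 up and 132 down of 187) and 32.9% after quantile normalization (49 up and 100 down of 149). The difference correlated with counted length at a Spearman rho of -0.478 across genes, and the called falls had a median length of 6038.5 bp. In a fit on only the 4 libraries compared, 2307 genes were called (830 up and 1477 down), 183 of the 183 among them. With 1 library left out, the count was 45 and 52 without untreated replicate 1 and 2, 1 and 1 without LPS replicate 1 and 2, 1427 and 1431 without anti-CD36 replicate 1 and 2, and 1 and 3 without combination replicate 1 and 2. Akap12 was called in each of these 8 fits, at 3.17 to 3.33.

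The combination against anti-CD36 shows the LPS response in the presence of the antibodies. Csf3 rose by 10.71 ± 0.25, Il1b by 9.75 ± 0.11, Ccl5 by 9.61 ± 0.28 and Il27, a cytokine of activated antigen-presenting cells, by 7.50 ± 0.15 (limma adjusted p from 1.8e-08 for Il1b to 6.1e-07 for Ccl5). Ranbp3l fell from an FPKM of 55.5 ± 1.25 to 0.709 ± 0.162 (log2 difference -5.05 ± 0.15), Selenbp1 changed by -4.33 ± 0.26 and Bnip3 by -2.93 ± 0.17. All 14 inflammatory cytokines rose (14 adjusted over the list alone, camera adjusted p = 6e-17), as did 19 of 22 NF-kB pathway genes (19 adjusted over the list alone, camera adjusted p = 1.05e-15). Of 40 interferon-stimulated genes, 32 rose and 1 fell (32 and 1 adjusted over the list alone, camera adjusted p = 1.1e-17). Cell cycle genes fell in 34 of 36 (35 adjusted over the list alone, camera adjusted p = 4.19e-12), with Mki67 at -2.50. These 4 lists were called with an estimated correlation as well (adjusted p = 0.0121, 0.0487, 0.0121 and 0.0375). Glycolysis and hypoxia genes fell in 16 of 24 and rose in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 0.000463, but adjusted p = 0.337 with an estimated correlation). Mitochondrial transcripts fell in 8 of 13 (8 adjusted over the list alone, camera adjusted p = 0.00982, but adjusted p = 0.608 with an estimated correlation), and without anti-CD36 replicate 1, the library with 15.8% of mitochondrial FPKM, the adjusted p was 0.0661. In all, 4844 genes were called (limma), 1580 higher and 3264 lower. With size factors the counts were 2382 and 2324 of 4706, and after quantile normalization 2068 and 2515 of 4583, so the share of rises went from 32.6% to 50.6% and 45.1%. The median of all genes was -0.15 as deposited and 0.02 with size factors, and without combination replicate 1 the count was 3216.

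Against untreated cells, the combination raised Csf3 by 10.44 ± 0.25, Il1b by 9.90 ± 0.11, Ccl22 by 7.77 ± 0.14 and Lcn2 by 7.12 ± 0.13 (limma adjusted p from 1.7e-08 for Il1b to 2.7e-07 for Csf3). Falls were found in Ranbp3l (-5.09 ± 0.15), Selenbp1 (-4.72 ± 0.26), Arrb1, the arrestin (-3.25 ± 0.11), and Bnip3, from 134 ± 1.42 to 14.3 ± 0.429 (-3.13 ± 0.17). Interferon-stimulated genes rose in 32 of 40 and fell in 1 (32 and 1 adjusted over the list alone, camera adjusted p = 2.2e-19, and adjusted p = 0.0109 with an estimated correlation). Cholesterol synthesis genes fell in 22 of 24 (22 adjusted over the list alone, camera adjusted p = 8.72e-05, but adjusted p = 0.118 with an estimated correlation), and glycolysis and hypoxia genes fell in 18 of 24 and rose in 1 (19 and 1 adjusted over the list alone, camera adjusted p = 0.000663, but adjusted p = 0.309 with an estimated correlation). Lipid handling genes of PPARg and LXR fell in 13 of 20 and rose in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.0538), Scd2 from 492 ± 2.33 to 60.4 ± 1.67 (log2 difference -3.01). In all, 6076 genes were called (limma), 1776 higher and 4300 lower. With size factors the counts were 2957 and 2915 of 5872, and after quantile normalization 2563 and 3124 of 5687, so the share of rises went from 29.2% to 50.4% and 45.1%. The median of all genes was -0.23 as deposited and 0.02 with size factors.

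Across the 5614 genes changed by LPS, the LPS effect with the antibodies was close in size to the effect without them. The slope of the first on the second was 0.906 (SD 0.047 over 16 pairs of single libraries, range 0.827 to 0.962), and it was 0.95 when the 4844 genes called with the antibodies were taken and the axes exchanged. In 157 of the 5614 the sign differed, 1619 had the larger effect with the antibodies, and 4028 were called with the same sign in both. Choosing genes by their effect without the antibodies pulls the slope under 1 by regression to the mean and lowers the count of 1619. These values thus do not show a weaker LPS response with the antibodies. The tested difference of these effects, the interaction, held 1 gene (limma, Benjamini-Hochberg), against 1396 at an unadjusted p under 0.05, where chance gives 514. It was Akap12, at 3.36 ± 0.15 (limma adjusted p = 0.00051). Among the uncalled genes Lcn2 had a value of 1.75 ± 0.18 (limma adjusted p = 0.098), Fos 1.34 (0.21), Ndrg1 -1.18 (0.21) and Bnip3 -1.17 (0.21). The count was 0 with a pseudocount of 0.1 (1301 unadjusted), where Akap12 had an adjusted p of 0.0547, and 615 and 237 without anti-CD36 replicate 1 and 2.

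**Figure D3:**
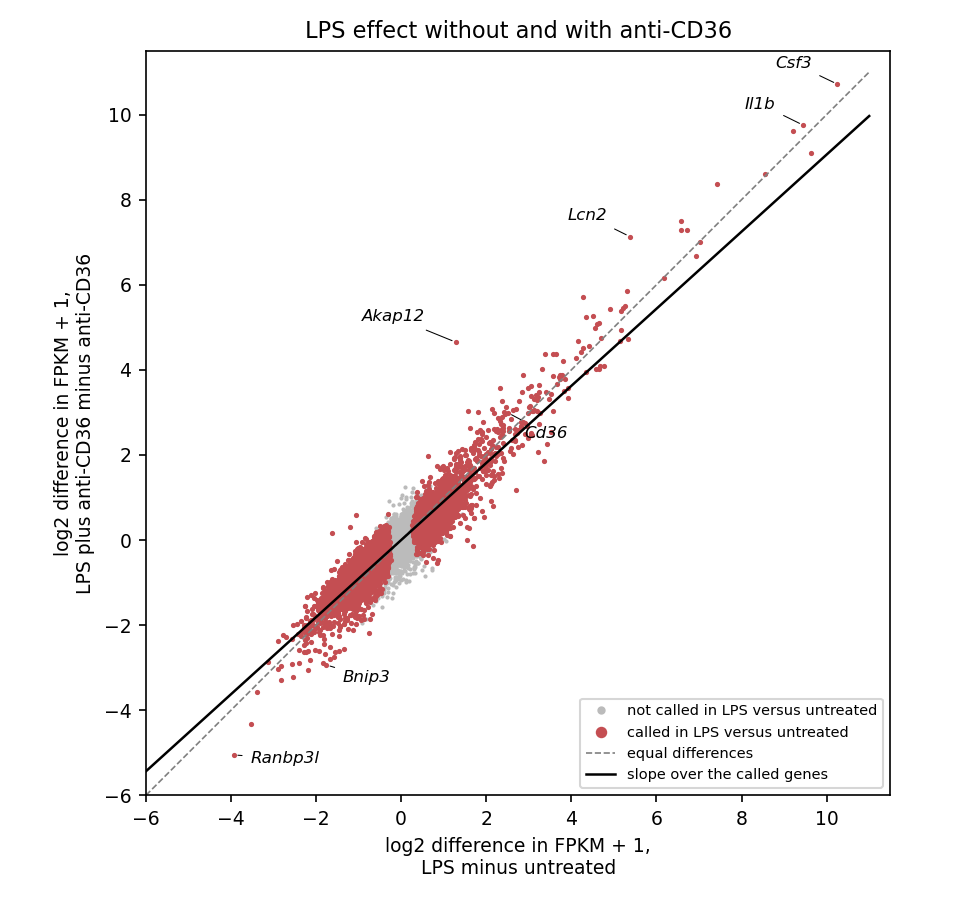
Log2(FPKM + 1) difference between the combination and anti-CD36 (vertical axis) against that between LPS and untreated cells (horizontal axis), with 1 point per tested gene. Genes called with LPS are red and the others grey. A dashed line marks equality and a black line the slope of 0.906 fitted over the called genes. The signs differ in 157 of the 5614 genes.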

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

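The tests with a length or GC trend removed use settings chosen after seeing the data. The results in this part stand out because they were called for the interaction, Akap12 by limma and gene lists by camera with the preset correlation. None of these lists was called by camera with an estimated correlation or by fry (fry adjusted p = 0.119 to 0.719). For the lists, a difference in the LPS effect between cells with and without the antibodies is thus uncertain.

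Akap12 was the single gene called for the interaction, at 3.36 on the log2 scale (limma adjusted p = 0.00051). Its FPKM was 0.216 ± 0.108 in untreated cells, 1.96 ± 0.0213 with LPS, 0.123 ± 0.0416 with anti-CD36 and 27.2 ± 2.19 with both (SD, n = 2). It was called in all 8 fits with 1 library left out (3.27 to 3.45), but not with a pseudocount of 0.1, where its adjusted p was 0.0547. Nitric oxide, prostaglandin and antimicrobial effectors had a median interaction of 0.33 (camera adjusted p = 0.0116, but adjusted p = 0.661 with an estimated correlation), and the call was lost without anti-CD36 replicate 1 (0.0523) or 2 (0.0911). Mitochondrial transcripts had a median interaction of -0.94 (camera adjusted p = 9.12e-05, but adjusted p = 0.661 with an estimated correlation), which was lost without anti-CD36 replicate 1 (0.241) and with the length trend removed (0.0579). Ribosomal proteins had a median interaction of -0.23 (camera adjusted p = 0.0116, but adjusted p = 0.698 with an estimated correlation). That call was lost without untreated replicate 2 (0.423), LPS replicate 1 (0.101) or combination replicate 2 (0.172), after quantile normalization (0.196) and without anti-CD36 replicate 2, where the direction turned (0.545). The interaction correlated with GC content across genes (Spearman rho 0.507), and so did the difference of the 2 combination replicates (0.605). With the GC trend removed the median was 0.30 for the effectors (camera adjusted p = 0.01), -0.36 for ribosomal proteins (0.00316) and -0.41 for glycolysis and hypoxia genes (5.91e-09), while none of the 13 mitochondrial transcripts had a GC value, so that list was not corrected.

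Glycolysis and hypoxia genes had a median interaction of -0.26 (camera adjusted p = 7.38e-05, but adjusted p = 0.661 with an estimated correlation), and in the combination against LPS their median was -0.43 (camera adjusted p = 7.03e-09, but adjusted p = 0.262 with an estimated correlation, so the fall of the list is itself uncertain). For the combination against LPS, the tables argue against a trend with gene length or GC content as the whole cause. The list's median there was -0.44 with both trends removed. They also argue against 1 odd library, since the median lay between -0.50 and -0.31 without each of the 4 libraries compared. Lower hypoxia signalling predicts that other targets of the hypoxia-inducible factors fall too, and 26 such genes outside the lists had a median of -0.50 with 4 called lower (camera p = 6.08e-07, but p = 0.0543 with an estimated correlation). The values are consistent with lower hypoxia signalling in the combination, as a hypothesis found and tested on the same libraries. Differences in cell density or oxygen between cultures were not tested and stay open.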

How the results depend on the processing

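The settings that leave out mitochondrial genes or remove a length or GC trend were chosen after seeing the data, and the others before. Unless the setting itself tests fewer genes or libraries, or adds a size threshold, the cause of a difference was not tested.

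The mean FPKM minimum of 5, which tests fewer genes, gave 3665 calls for LPS, 811 for anti-CD36, 88 for the combination against LPS, 3098 against anti-CD36 and 3927 against untreated cells. A difference of at least 1 left 1712, 61, 37, 1391 and 1976. In a fit on only the groups compared, anti-CD36 had 0 calls (limma, 2045 at an unadjusted p under 0.05) and the combination against LPS 2307. Anti-CD36 had 838 calls with mitochondrial genes left out and 748 with the length trend removed. The interaction had 0 calls with a pseudocount of 0.1 (limma, 1301 unadjusted), 6 with a pseudocount of 5 and 2 with the length trend removed. Apart from the block and the left-out libraries, the other settings moved no count of called genes by more than 1.5 times.

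With an estimated correlation, camera called 4 lists for LPS, 0 for anti-CD36, 0 for the combination against LPS, 6 against anti-CD36, 4 against untreated cells and 0 for the interaction, in place of 13, 7, 7, 16, 13 and 4. Fry, which does not compare a list with other genes, called 21 for LPS and 0 for the interaction.

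With each library left out in turn, a group with 1 library left is assumed to vary like the others. Calls then ran from 3598 to 7091 for LPS, 0 to 3730 for anti-CD36, 1 to 1431 for the combination against LPS, 3216 to 6381 against anti-CD36, 4432 to 7419 against untreated cells and 1 to 615 for the interaction. The extremes were 3598 without LPS replicate 1, 0 without either untreated library, 3730 without anti-CD36 replicate 1, 1 without either LPS library or combination replicate 1, 1431 without anti-CD36 replicate 2, 3216 without combination replicate 1 and 615 without anti-CD36 replicate 1. Lists called ran from 12 to 14, 4 to 7, 5 to 9, 14 to 16, 13 to 14 and 2 to 4, in the order of the comparisons above. The anti-CD36 count of 4 was without anti-CD36 replicate 1, and the interaction count of 2 without anti-CD36 replicate 2. The slope of the LPS effect with on without the antibodies ran from 0.846 to 0.954, without anti-CD36 replicate 1 and 2, and the LPS effect on Cd36 from 2.41 to 2.61. Of 65 named genes called with anti-CD36, 65 lost the call without either untreated library, 38 without either LPS library, 28 and 27 without combination replicate 1 and 2, 27 with the length trend removed, 18 after quantile normalization, 17 with mitochondrial genes left out, 15 with size factors and 12 with a replicate block. Of 37 in the combination against LPS, 36 lost it without LPS replicate 1, LPS replicate 2 or combination replicate 1, and 34 without combination replicate 2. There 20 and 19 lost it without untreated replicate 1 and 2, 20 with a replicate block, 15 with a pseudocount of 0.1, 10 after quantile normalization, 10 with mitochondrial genes left out, 7 with the length trend removed and 3 with size factors. None of the called named genes turned direction in the settings run for single genes.

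The reversed values were in uncalled differences. Tlr4 with anti-CD36 (-0.08) was at 0.042 after quantile normalization, 0.012 with size factors, 0.07 with the length trend removed and 0.041 without untreated replicate 2, in a range from -0.202 to 0.041 with 1 library left out. The interaction of Cd36 (0.49) was at -0.037 with a pseudocount of 0.1, where the LPS effect on Cd36 was 4.91.

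The replicate differences of 2 groups correlated across genes at -0.645 (untreated and anti-CD36) to 0.53 (untreated and combination). Libraries of some groups thus shared a difference that the model leaves out, and its cause was not tested. Equal replicate numbers did not mark it with the same sign in all groups. A replicate block assumes the same sign in each group, so it does not remove this difference. With a replicate block the count was 863 for anti-CD36 and 46 for the combination against LPS, and the other counts moved by less than 1.5 times.

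Depth limits the lowest genes. Cd36 in untreated cells rests on about 8 and 30 reads, so its fold depends on the pseudocount.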

Other observations

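The tests for endotoxin in the antibody and for the same rise without LPS, the settings that leave out mitochondrial genes or remove the length trend, and the overlaps by gene length, by spread, in separate fits and in opposite directions, were chosen after the results were seen.

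The genes that differed with the antibodies overlapped between resting and LPS-treated cells. Of the 1092 genes lower with anti-CD36 alone and the 146 lower in the combination than in LPS, 83 were the same, where independent lists give 15.5. The shared genes included Pdpr, Ago2, Abl2, Scd2, Atp7a, Kcnj2, Cflar and Pfkfb3. Of the 313 and 37 higher genes, 3 were shared, Serpinb6b, Rpp38 and Apip, where independent lists give 1.1 (Fisher's exact test across genes, which are not independent, p = 0.102). These comparisons use different libraries on both sides but share 1 spread per gene, so a gene with a small spread is called more easily in both, and 15.5 is too low a value for chance. Lists independent within 20 bins of that spread give 21.3, and within 100 bins of spread and length 27.5. In opposite directions, which a shared spread would favour as well, 0 and 1 genes were shared. In separate fits on only the groups compared, at an unadjusted p under 0.05 (no gene was called for anti-CD36 after adjustment), 1537 and 2223 genes were lower and 839 were shared, where independent lists give 332.1 and lists independent within bins of spread and length 486.9. In the same fits 508 and 1536 genes were higher and 155 were shared, against 75.8 and 101.4 by the same expectations. The antibody effects correlated at r = 0.471 and rho = 0.484 over the 10289 genes. Both effects also followed gene length (Spearman rho -0.445 and -0.478), with a median of 7301 and 6038.5 bp in the called falls against 4329 bp in all tested genes. Lists independent within 20 bins of length give 22.5 shared falls. With the length trend removed, 354 and 99 genes were lower and 32 were shared, where independent lists give 3.4 and lists independent within bins of spread 4.5. Of 394 and 32 higher genes 4 were then shared, where independent lists give 1.2, and in the separate fits 368 falls and 224 rises were, where they give 132.7 and 123.4. The correlation was r = 0.346. By these tests a common length trend or a shared spread accounts for part of the overlap and not for all of it. Other differences between libraries that no treatment explains were not tested as a cause. Replicate differences of unlike groups, which share no library, correlated across genes at -0.645 to 0.53. Such differences could give an overlap in the same direction too, so a shared antibody effect is not set apart from them. The counts of called genes in both comparisons depend on which libraries share the estimate of the spread. Leaving out 1 library lowered or raised them, according to the library.

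Of 9 scavenger receptors, 1 rose and 3 fell with anti-CD36 alone (2 and 3 adjusted over the list alone, camera adjusted p = 0.822). Msr1, a receptor for modified lipoproteins, rose by 0.75, while Lrp1 was at -1.39 and Scarb1, a receptor for high-density lipoprotein, at -0.49. Of 20 genes for Fc receptors, phagocytosis and integrins, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.448). Fcer1g, the signalling chain shared by activating Fc receptors, rose by 0.77, and the integrin subunit Itgav (-0.95), the bridging ligand Gas6 (-0.65) and the kinase Syk (-0.50) were lower. Of 24 glycolysis and hypoxia genes, Hk2 (-0.71) and Pfkfb3 (-0.57) were lower (4 adjusted over the list alone, camera adjusted p = 0.259).

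The 1092 genes lower with anti-CD36 alone had a median log2 difference of -0.58. More mitochondrial RNA in anti-CD36 replicate 1 is not the whole cause by the test made, since the median was -0.51 with mitochondrial genes left out. A trend with gene length could be part of it: with the trend removed the median was -0.39, between the bounds set for and against, and 335 of the 1092 were still called lower, so how much of the falls of the set came with length stays open. The trend is also one between libraries of the same group, with a rho of -0.478 between the untreated replicates and 0.322 between the anti-CD36 replicates, against -0.445 for the comparison. In other libraries, the combination against LPS, the same genes had a median of -0.27 (-0.12 with the length trend removed, against 0.02 for the other 9197 genes), as an effect of the antibodies in any state of the cells predicts, and as a length trend common to both comparisons would give in part. Other differences between libraries that no treatment explains could give such a median too.

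Interferon-stimulated genes had a median of 0.29 in the combination against LPS, with 3 of 40 called higher (camera adjusted p = 3.01e-09), but the list's call was lost with an estimated correlation (adjusted p = 0.0831), so the rise of the list is itself uncertain. Endotoxin in the antibody would raise the strongest LPS targets in cells given anti-CD36 alone, but the 20 genes that LPS raised by at least 5 (median 6.58) had a median of 0.03 there (quartiles -0.09 and 0.15). Several were under an FPKM of 1 in both groups, such as Ccl22 (0.275 untreated, 0.807 with anti-CD36) and Lif (0.131 and 0.0624). For such genes this scale understates a change, so a small rise is not excluded. Among more abundant ones, Ccl3 was at 39.9 and 37.4, Ccl4 at 26.1 and 28.8, and Acod1 at 19.2 and 22.4. An overall scale by size factors does not account for the list's rise in the combination, since its median was 0.35 with them. They moved the median of all genes in this comparison only from -0.019 to 0.025. This does not cover trends with gene length or GC content. Whether the list rose alike without LPS stays open: with anti-CD36 alone it had a median of 0.17 (4 higher and 2 lower of 40, camera p = 1.04e-05, but adjusted p = 0.222 with an estimated correlation), and Phf11d and Ifi44, which rose there, were at an FPKM of 34.4 and 57.7 with LPS and 34.8 and 56.5 with both. An effect of antibody in general stays open as well, since none of the 4 groups had an antibody of another specificity.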
